A study of Homo sapiens with 6 samples.

How the data were processed

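K562 cells, a human chronic myeloid leukaemia line grown in RPMI1640 with 10% serum, were sampled as parental cells, as parental cells given 225 ng/ml doxorubicin for 48 h, and as 4 drug-tolerant clones. Per the labels' protocols, RNA was taken with TRIzol and stranded poly(A) libraries were made with a TruSeq kit. The labels name 1 parental sample and 2 parental libraries, and each of the 2 deposited tables holds 1 of them. The series' text gives the drug unit as ng/ul in 1 place where the samples' protocols give ng/ml, and ng/ml is used here.

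The deposited tables hold whole counts of reads per gene, to each of which the authors added 1, and a pair of libraries that both have no read is given as missing. The added 1 was subtracted and missing pairs were read as 0, which was checked on the table of the clones, where the 4 copies of Parental_1 are identical. The deposited log2 fold changes are the authors' log2 ratio of each pair of values less the log2 ratio of the summed values of that pair, and they were checked but not used further. The aligner, the counting program, its use of strand and their versions are not given in the sources used here. The genome build is GRCh38 per the submitters' processing notes, but the gene positions in the tables are not of that build: only 609 of 35158 genes start within 10 bases of their GRCh38 position. Positions were therefore taken by Ensembl ID from GENCODE 29, and none from the tables. There are 34796 genes in the table of the clones, 33312 in that of the 48 h library and 30341 in both; 22320 genes were named by the tables, 13255 by GENCODE 29, and 2192 have no symbol. No column of per-sample values was left unused.

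The 4 clones were compared with Parental_1 by edgeR 4.0.16 (quasi-likelihood, TMM scaling, its own filter on low counts, Benjamini-Hochberg adjustment at 0.05, R 4.3.3), which tested 18300 genes with 3 residual degrees of freedom. The common biological coefficient of variation was 0.429. It was 0.501 in the median of the 1474 genes 2-fold apart in one direction in all clones and 0.373 in the others. The SE printed after ± on a log2 fold change is the absolute fold change divided by the square root of the test's F statistic. It was worked back from the test and is not an error estimated by the model. Log2 ratios per library used a prior count of 2. The 48 h library was set against Parental_2 without a test, among genes with at least 20 counts in the higher library, with 95% intervals from the counts. A fold against a library at 0 used a floor of 3 counts in that library. Where counts were added across tables, genes were joined by Ensembl ID and the libraries scaled together.

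The 28 gene lists were p53 targets, drug efflux transporters, ABCB1 neighbours on 7q21, anthracycline targets and metabolism, DNA repair, histone methyltransferases and demethylases, erythroid, megakaryocytic, granulocytic and monocytic, stem and progenitor, lymphoid, epithelial and fibroblast, proliferation, histone genes, interferon response, antigen presentation, NF-kB and inflammatory, BCL2 family, integrated stress, NRF2, cholesterol and fatty acid synthesis, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis and hypoxia, lysosome and autophagy, mesenchymal and adhesion, STAT5, ERK and MYC outputs, and HOX genes. For the clones they were tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry. At 48 h each list's median was placed among 10000 random lists of the same size matched on expression. Named genes followed a rule set in advance: ABCB1, TOP2A and TOP2B, the 8 largest changes each way among called genes, up to 2 members of each list each way, the 8 highest and 8 lowest ratios at 48 h, and the 5 genes with the largest range between clones. No gene was called for the clones, so each list is represented by its smallest p. The highest and lowest genes there were ranked by the weakest ratio of any clone to either parental library, after their values were seen.

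Expression along chromosomes was scanned with running medians of 15 expressed genes against 100 permutations of gene order. Simulated values for the correlation between comparisons came from 50 simulations of unchanged groups, with every library drawn independently. Alternatives tried were DESeq2 1.42.0, limma-voom, other scalings and filters, each clone left out, the 48 h library added to the fit, other prior counts and, added later, the other parental library or both and all settings for named genes at 48 h.

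The tests were run on simulated counts made for the clones against parental cells, drawn from the real means and library sizes. With changed genes drawn from any expressed genes, edgeR (17538 genes) recovered 38.8% at 4-fold, 91.0% at 16-fold and 98.5% at 64-fold, with 6.79% of calls false, and DESeq2 (18300 genes) 68.7%, 89.6% and 93.9%, with 35.4% false. With changed genes drawn from those 2-fold apart in all clones, edgeR (17452 genes) recovered 11.9%, 70.1% and 93.9%, with 8.59% false, and with both parental libraries (16856 genes) 34.3%, 95.5% and 98.5%. A simulated list of 25 genes raised by 1 on the log2 scale gave a camera p of 1.02e-07 and an unchanged list 0.734. Genes were drawn independently there and only the preset correlation was run. The simulation therefore cannot show how either form of camera behaves on lists whose genes vary together.

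Total counts ranged from 12537146 to 21361758 per library. On TMM-scaled library sizes 3 counts correspond to 0.134 to 0.259 CPM. PCR copies are not marked, so intervals and floors cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Reads were not analysed here.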

Results

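Gene expression was measured by RNA sequencing in K562, a human cell line from a chronic myeloid leukaemia, to ask how the transcriptional state of cells that tolerate doxorubicin differs from that of sensitive cells. Doxorubicin is an anthracycline that traps topoisomerase II on DNA. The 6 samples were untreated parental cells, parental cells exposed to 225 ng/ml doxorubicin for 48 h, and 4 clones named ATC1 to ATC4. The clones were recovered from 480 wells of 10000 cells each. Of these, 21 wells survived 4 weeks of drug, first at 100 ng/ml and then at 225 ng/ml, and 4 were kept at 225 ng/ml. The parental sample had 2 libraries, Parental_1 in the table of the clones and Parental_2 in the 48 h table, so the clones are set against Parental_1 and the 48 h library against Parental_2. These 2 libraries differed from each other by more than sampling noise. The mean chi-square was 61.35 per gene over 14195 genes, where 1 is sampling noise. In Parental_2, 706 of 13324 genes were at least 2-fold higher and 777 at least 2-fold lower.

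Total counts per library were 20895918 in Parental_1, 21361758 in ATC1, 18420238 in ATC2, 21252948 in ATC3, 19169282 in ATC4, 12537146 in Parental_2 and 14146994 in the 48 h library. Mitochondrially encoded genes took 5.07% of the counts in Parental_1, 6.83%, 5.07%, 9.63% and 6.05% in ATC1 to ATC4, 4.25% in Parental_2 and 7.49% in the 48 h library. MIR4485, which lies in a nuclear copy of mitochondrial ribosomal RNA and can share reads with it, was the most abundant gene in ATC3 (2.07% of counts) and in the 48 h library (1.83%). Gene positions are given in GRCh38.

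All 4 clones carried far more ABCB1, the P-glycoprotein pump that carries doxorubicin out of cells, than parental cells. ABCB1 (ENSG00000085563, chromosome 7, 87503633 to 87713323) reached 454, 2180, 396 and 757 CPM (TMM-scaled counts relative to library size) in ATC1 to ATC4 against 2.76 CPM in Parental_1, a mean of 947 ± 838 CPM (SD, n = 4) and a 343-fold difference of means. Its log2 fold change was 8.43 ± 1.55 (SE, here and below worked back from the test's F statistic), and it was higher in 4 of 4 clones. Both topoisomerase II genes, which encode the targets of doxorubicin, were below Parental_1 in the mean. TOP2A (ENSG00000131747, chromosome 17, 40388516 to 40417950) measured 376 ± 168 CPM (SD, n = 4) against 653 CPM, with a log2 fold change of -0.79 ± 0.48 (SE), and in ATC4 its log2 ratio was -0.06. TOP2B (ENSG00000077097, chromosome 3, 25597905 to 25664907) measured 278 ± 50.8 CPM (SD, n = 4) against 459 CPM, with a log2 fold change of -0.71 ± 0.32 (SE). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.254 for ABCB1, 0.528 for TOP2A and 0.433 for TOP2B, so none of the 3 passed 0.05. ABCB1 passed in DESeq2 (adjusted p = 8.93e-17) and in edgeR's test with both parental libraries (adjusted p = 0.0148), which counts 2 libraries of 1 sample as replicates, and over its alternatives the adjusted p ranged from 4.8e-41 to 0.414.

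Across 18300 tested genes, edgeR's quasi-likelihood test of the 4 clones against Parental_1 called 0 genes higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.14. At an unadjusted p under 0.05 it gave 1372 genes higher and 784 lower. Scaling by library totals gave 1710 and 364 and moved the median log2 fold change of all genes from 0.11 to 0.29. DESeq2 called 448 higher and 95 lower, and limma-voom 0 and 0. With both parental libraries as separate replicates edgeR called 252 and 96, of which 224 and 63 were also called by DESeq2. These are 2 libraries of 1 sample, so the added degree of freedom is not a separate sample. Leaving out ATC4 gave 49 genes higher and 35 lower in edgeR. On counts simulated for this design, with changed genes as variable as those that stood apart in all clones, the same test recovered 11.9% of genes at 4-fold, 70.1% at 16-fold and 93.9% at 64-fold. In that simulation 38.2% of DESeq2's calls were false, over 18300 genes, where the real data gave DESeq2 34437. In the real test ABCB1, at 343-fold, was not called, so the simulated shares may not hold for these data. The p-values measure the spread between clones, and the single parental library is assumed to vary as the clones do.

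Counted per clone without a test, 2714 of 15916 genes were at least 2-fold higher in ATC1, 3183 in ATC2, 2549 in ATC3 and 2395 in ATC4, and 969, 1696, 1425 and 922 were at least 2-fold lower. In all 4 clones together 1068 genes were at least 2-fold higher and 167 lower, and 682 and 94 of them were so against both parental libraries. Thinned to 12537146 counts each, ATC1 to ATC4 had 9.6%, 11.6%, 2.2% and 9.0% more genes with a read than Parental_1. The genes named in this paragraph were chosen after their values were seen, since no gene passed the test. TFPI2, a secreted protease inhibitor, had 0 counts in Parental_1 and was at least 126-fold higher in the mean of the clones, against a floor of 3 counts. GBP5, an interferon-inducible guanylate-binding protein, was 221-fold higher (log2 fold change 7.79 ± 1.65), and CAMK2D, a calcium/calmodulin-dependent kinase, had 328, 214, 238 and 423 counts in the clones against 2 (log2 fold change 7.03 ± 0.84). ADAMTS20 and MGAT5B were 64-fold and 41.8-fold higher. The lowest included ALDH1A1, a retinaldehyde dehydrogenase, at 0.544 ± 0.277 CPM (SD, n = 4) against 32.0 CPM (log2 fold change -5.86 ± 0.58). The amino acid transporter SLC6A19 was at 0.798 ± 0.236 CPM against 32.5 CPM (-5.33 ± 0.46), and FN1, fibronectin, at 3.80 ± 1.90 CPM against 63.8 CPM (-4.06 ± 0.53). GABRG1 had a log2 fold change of -5.09 ± 0.78, COBL of -6.97 ± 0.77 and SLC16A9 of -4.92 ± 0.60. These sizes depend on the parental library, since Parental_1 and Parental_2 had 187 and 16 counts of COBL, 549 and 89 of SLC16A9 and 611 and 134 of SLC6A19. The weakest ratio of a clone to either library was -2.77, -2.28 and -3.33, but the lowest genes were chosen on that ratio, so it is no separate check. The adjusted p in edgeR's quasi-likelihood test was 0.14 for SLC6A19, 0.171 for ALDH1A1, 0.199 for TFPI2, CAMK2D and FN1, and 0.277 for GBP5.

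**Figure D1:**
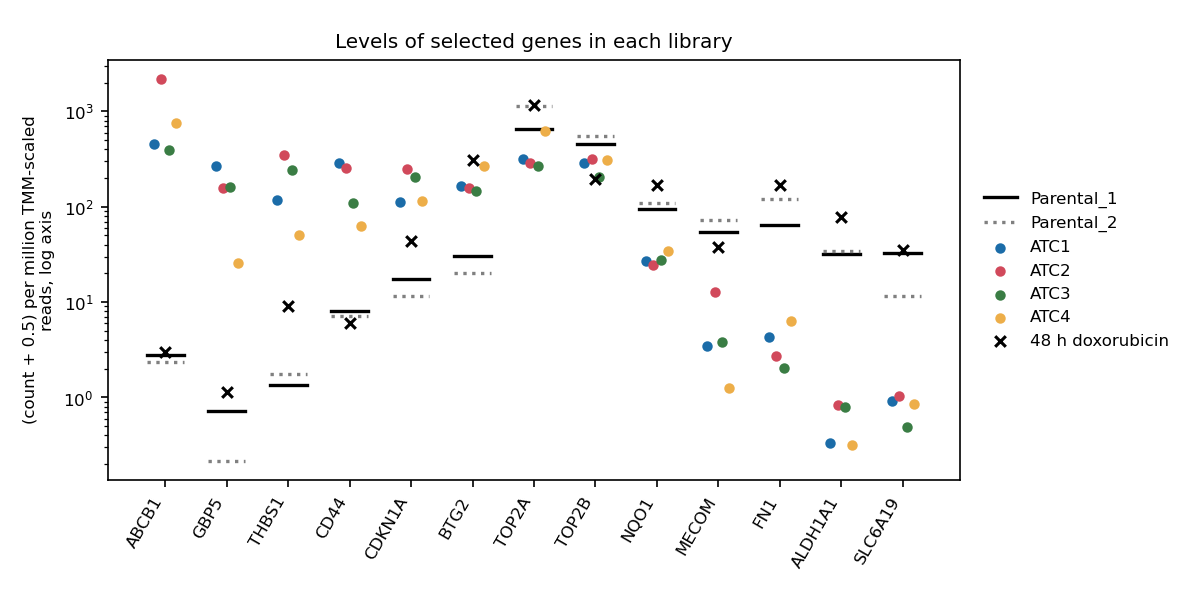
Levels of selected genes in each library on a log axis, as CPM of counts plus 0.5 with TMM scaling, with the clones and Parental_1 scaled in their own table and Parental_2 and the 48 h library in theirs. Points are the 4 clones, crosses the 48 h library, bars the parental libraries; ABCB1 lies between 396 and 2180 CPM in the clones and at 2.76 CPM in Parental_1.

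Gene lists fixed before the data were examined were compared with all other genes by camera, and 14 of 28 passed an adjusted p of 0.05 with camera's preset correlation. None of the 14 passed with an estimated correlation. Among these 14 the estimate ran from -0.01 for granulocyte and monocyte genes to 0.94 for the ABCB1 neighbours, against the preset 0.01. Over all genes tested no list had a called member, higher or lower. Megakaryocyte genes stood highest (camera adjusted p = 1.52e-07; adjusted p = 0.472 with an estimated correlation). Of 23 measured members, 12 were at least 2-fold higher in all 4 clones and 1 lower, and adjusted over the list alone 12 passed higher and 1 lower. THBS1, thrombospondin stored in platelets, was 143-fold higher (log2 fold change 7.17 ± 1.44), and F2R, the platelet thrombin receptor, 3.45-fold higher (1.80 ± 0.40). The list's median log2 ratio was 3.01, 3.10, 4.38 and 1.29 in ATC1 to ATC4, or 2.68, 2.49, 4.29 and 1.29 with the 4 members at 0 in Parental_1 set at their bound. The NF-kB and inflammatory list was higher (adjusted p = 0.000914; adjusted p = 0.528 with an estimated correlation), with medians of 0.54, 2.10, 1.25 and 0.38, or 0.49, 1.91, 1.25 and 0.36 at the bound. TRAF1, a TNF receptor adaptor, had a log2 fold change of 3.81 ± 0.90 and the chemokine CCL2 of 5.12 ± 1.41. CCL2 had 2 counts in Parental_1 and 8 in Parental_2, and with both its log2 fold change was 3.40 ± 1.00 and its weakest ratio 0.57. Interferon response genes were higher (adjusted p = 0.00202; adjusted p = 0.472 with an estimated correlation), with the antiviral RSAD2 at 1.98 ± 0.63 and HERC6 at 3.45 ± 1.19, with 3 counts in Parental_1 and 6 in Parental_2. Antigen presentation genes were higher (adjusted p = 0.029; adjusted p = 0.472 with an estimated correlation), with HLA-C at 1.61 ± 0.48, or 2.20 with both parental libraries, and did not pass without ATC4 (adjusted p = 0.0943).

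Among p53 targets, 4 of 22 measured members passed higher when adjusted over the list alone and 0 lower, and the list was higher in camera (adjusted p = 0.0237; adjusted p = 0.472 with an estimated correlation). The list did not pass without ATC3 (adjusted p = 0.0677), with both parental libraries (0.0956) or with Parental_2 in place of Parental_1 (0.509, median log2 fold change 0.07 in place of 0.31). The cell cycle inhibitor CDKN1A measured 170 ± 69.3 CPM (SD, n = 4) against 17.4 CPM in Parental_1, a log2 fold change of 3.30 ± 0.64, and the antiproliferative BTG2 185 ± 54.5 CPM against 30.2 CPM, a log2 fold change of 2.62 ± 0.47. Their adjusted p in edgeR's quasi-likelihood test was 0.271 and 0.251, and 0.0169 and 0.0148 with both libraries of the parental sample as replicates. Granulocyte and monocyte genes were higher in camera (adjusted p = 0.0442; adjusted p = 0.472 with an estimated correlation), with the myeloid regulator SPI1 at 0.78 ± 0.32. They did not pass without ATC3 (adjusted p = 0.1), without ATC4 (0.0623) or with both parental libraries (0.432), and with Parental_2 their median turned from 0.76 to -0.35. The 13 measured genes next to ABCB1 on 7q21, ABCB1 included, were higher in camera (adjusted p = 0.0118, or 0.63 with an estimated correlation). Only ABCB1 itself passed over the list alone, and the list's medians were 0.51, 2.66, 0.35 and 1.66 in ATC1 to ATC4. The list did not pass in camera without ATC4 (adjusted p = 0.0533) or with Parental_2 (0.0581). RUNDC3B, which overlaps ABCB1, had 7, 301, 25 and 232 counts against 1 in Parental_1 and 5 in Parental_2. Strand use in counting is not given in the sources used here, so reads of these overlapping genes cannot be separated.

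Lower lists were led by cholesterol and fatty acid synthesis (camera adjusted p = 3.47e-06; adjusted p = 0.472 with an estimated correlation), with medians of -0.64, -1.58, -0.78 and -0.73 in ATC1 to ATC4 and 0 members passing over the list alone. SQLE, squalene epoxidase, lay the other way at 408 ± 50 CPM (SD, n = 4) against 173 CPM. Proliferation genes were lower (adjusted p = 1.02e-05; adjusted p = 0.472 with an estimated correlation), with cyclin A2, CCNA2, at -1.03 ± 0.27 and the ribonucleotide reductase subunit RRM1 at -1.01 ± 0.29. DNA repair genes were lower (adjusted p = 0.000373; adjusted p = 0.472 with an estimated correlation), with PARP1 at -1.29 ± 0.31 and the exonuclease EXO1 at -1.12 ± 0.34. NRF2 and oxidative stress genes were lower (adjusted p = 0.000373; adjusted p = 0.472 with an estimated correlation), and NQO1, a quinone reductase, passed over the list alone at 28.2 ± 4.38 CPM (SD, n = 4) against 93.8 CPM. Nuclear genes of oxidative phosphorylation were lower (adjusted p = 0.000373; adjusted p = 0.596 with an estimated correlation), with TFAM at -0.92 ± 0.32, and their median ratio was -0.45, -0.79, -0.08 and -0.43 beside the mitochondrial shares of counts given for each library. Histone methyltransferases and demethylases were lower (adjusted p = 0.00563; adjusted p = 0.472 with an estimated correlation), with MECOM at -3.34 ± 0.89 and EED at -1.08 ± 0.35. Anthracycline targets and metabolism genes were lower (adjusted p = 0.0136; adjusted p = 0.472 with an estimated correlation), with 1 higher and 2 lower over the list alone, and the aldose reductase AKR1B1 lay the other way at 3.33 ± 0.61.

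The other 14 lists did not pass in camera. The adjusted p was 0.0514 for epithelial and fibroblast genes, 0.0514 for glycolysis and hypoxia, 0.097 for drug efflux transporters, 0.097 for histone genes, 0.127 for lymphoid genes, 0.187 for the integrated stress and unfolded protein response, and 0.213 for lysosome and autophagy. It was 0.309 for the BCL2 family, 0.497 for STAT5, ERK and MYC outputs, 0.658 for mesenchymal and adhesion genes, 0.768 for stem and progenitor genes, and 0.784 for erythroid, mitochondrially encoded and HOX genes. With Parental_2 in place of Parental_1, integrated stress genes turned from a median of 0.40 to -0.84. They passed lower there with the preset correlation but not with an estimated one. Erythroid genes (median 0.80) passed higher with Parental_2 and HOX genes (median -0.25) lower, again only with the preset correlation. Adjusted over the list alone, glycolysis had 1 member higher and 2 lower, drug efflux 1 higher, which was ABCB1, stem and progenitor genes 1 higher and 1 lower, and mesenchymal genes 2 lower, while lists given without such a count had 0. The glycolytic enzymes HK2 and LDHA had log2 fold changes of -1.41 ± 0.28 and -1.67 ± 0.34, the transporter ABCC3 of 4.61 ± 1.68, the adhesion receptor CD44 of 4.49 ± 1.05 and vimentin, VIM, of -1.25 ± 0.28, or -1.87 with both parental libraries. JUN was at 1.68 ± 0.43, the RAS pathway inhibitor SPRED1 at -1.54 ± 0.32 and the proapoptotic BMF at 1.87 ± 0.48. Mean and median differed in sign for the erythroid list (mean 0.10, median -0.05), the HOX list (mean -0.09, median 0.06) and the mesenchymal list (mean -0.43, median 0.08).

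**Figure D2:**
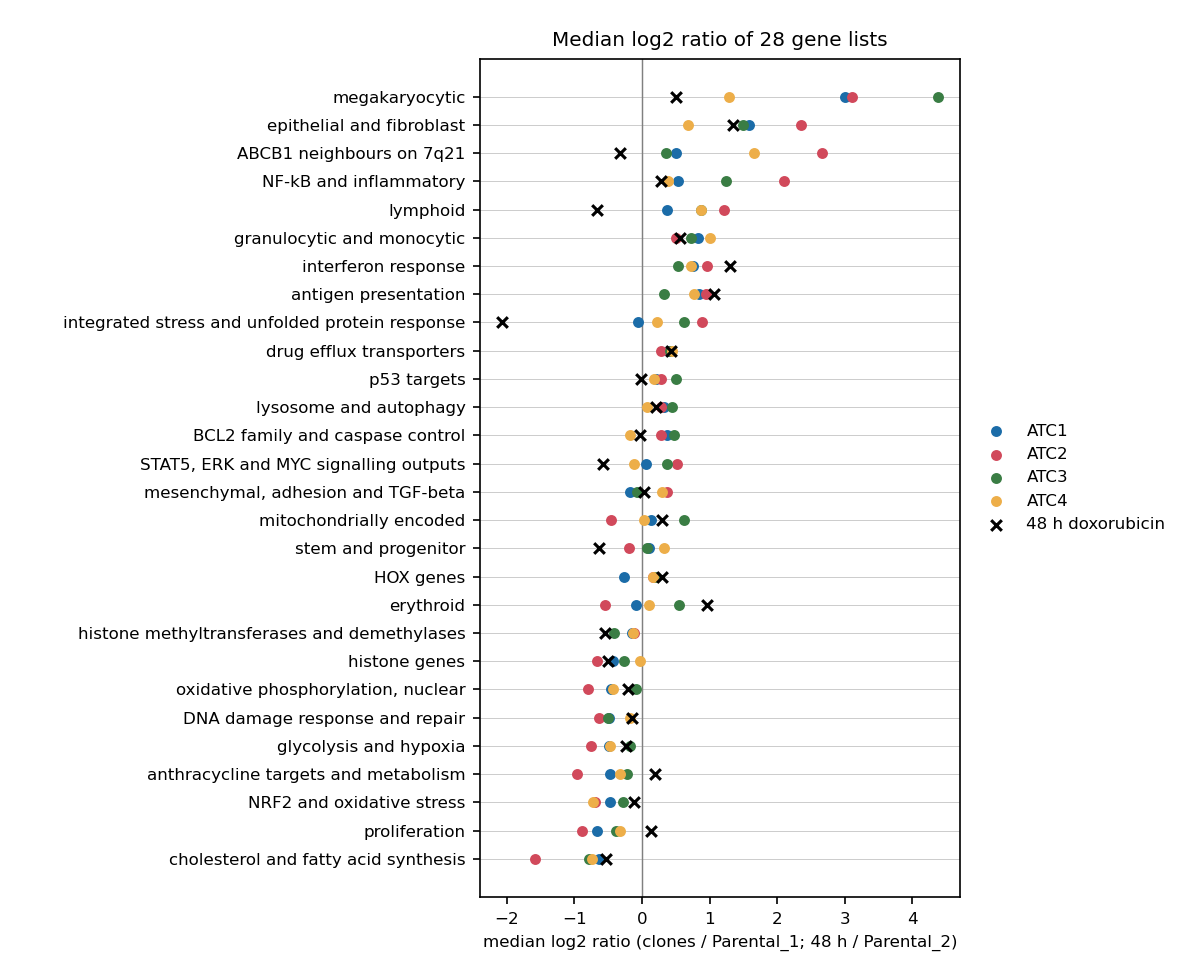
Median log2 ratio of each of the 28 gene lists, with 1 point per clone against Parental_1 and a cross for the 48 h library against Parental_2. Megakaryocyte genes lie between 1.29 and 4.38 in the clones and at 0.50 at 48 h, and integrated stress genes at -2.07 at 48 h.

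The clones also differed from each other. PPBP, a platelet chemokine, had 50, 919, 1229 and 0 counts in ATC1 to ATC4 and 0 in Parental_1. S100A6, a calcium-binding protein, had 4, 3, 2 and 1264 counts against 687, and the imprinted RNA H19 had 17, 6, 24 and 2338 against 208. The sodium channel SCN9A had 114, 613, 0 and 213 counts against 448, and MYCT1 had 42, 639, 174 and 0 against 2. On chromosome 7 the 8 expressed neighbours of ABCB1, without ABCB1 and its paralog ABCB4, had median log2 ratios relative to all genes of 0.23, 2.70, 0.34 and 1.62. These stood at percentiles 78.29, 99.72, 84.02 and 99.54 of 10338 runs of adjacent genes in the same clone. A block of 54 genes from HSPB1 to BAIAP2L1 (chromosome 7, 76302544 to 98401068, 22.1 Mb) stood out in ATC2. Its medians were 0.32, 1.44, 0.18 and 1.53, with 88.9% of its genes above the clone's median in ATC2 and in ATC4. This block was found in the data, and the difference between clones was not tested.

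**Figure D3:**
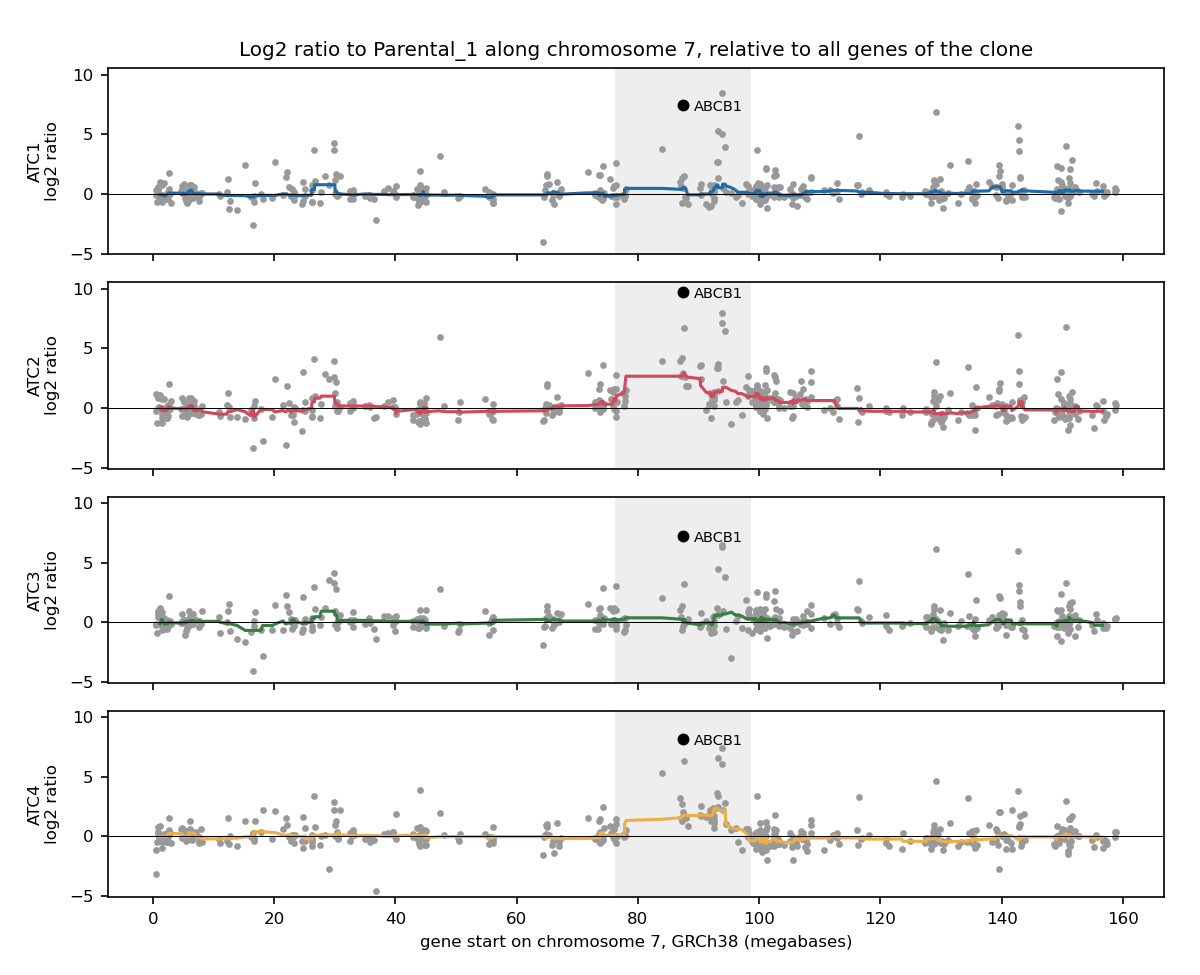
Log2 ratio to Parental_1 of each expressed gene along chromosome 7 (position in megabases, GRCh38) in each clone, relative to the clone's median, with the running median of 15 genes as a line. The shaded block of 54 genes has medians of 1.44 in ATC2 and 1.53 in ATC4, and of 0.32 in ATC1 and 0.18 in ATC3.

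The library of parental cells after 48 h of doxorubicin was compared with Parental_2, 1 library each. It held more of several transcripts of epithelial, interferon and red cell type and less of amino acid stress genes. CPXM1, a carboxypeptidase family member, had 2025 counts against 11 in Parental_2, 139-fold (95% interval 77.5 to 279), and BTG2 15.4-fold more (13.5 to 17.6). Against a floor of 3 counts the epithelial TRIM29 was at least 65.4-fold higher, RARRES3 at least 42.5-fold, FAIM2 at least 32.9-fold and SFRP5 at least 32.7-fold. These bounds hold for Parental_2, where the 4 genes had 0 counts; Parental_1 had 4, 15, 3 and 5, with log2 ratios of 5.73, 3.62, 5.01 and 4.52. SPINK4 had 798 counts against 2 (log2 ratio 7.34, 6.38 to 11.28), PGLYRP4 406 against 3 (6.03, 5.12 to 8.96) and the epithelial factor ELF3 222 against 1 (5.96, 4.90 to 12.70). CHAC1, a glutathione-degrading enzyme induced by ATF4, stood at 14 counts against 662 (log2 ratio -5.76, -6.85 to -5.21), INHBE at 28 against 864 (-5.24) and the cystine transporter SLC7A11 at 152 against 2599 (-4.48, -4.75 to -4.27). ADM2, ASS1, AKNA and GABRG1 had ratios of -4.67, -4.51, -4.41 and -4.38, and the pseudogene ASNSP1, whose reads cannot be separated from those of ASNS, of -5.43. Against Parental_1 these differences were smaller, at -3.84 for CHAC1, -2.49 for INHBE, -2.74 for SLC7A11, -2.27 for ADM2, -2.52 for ASS1, -1.91 for AKNA, -3.49 for GABRG1 and -3.41 for ASNSP1. ABCB1 had 46 counts against 27 (log2 ratio 0.34, -0.35 to 1.10), a difference not detectable at this depth, TOP2A was at 0.03 (0.00 to 0.06) and TOP2B at -1.51 (-1.57 to -1.45). Against Parental_1 TOP2A was at 0.85, so its level relative to parental cells depends on the library used.

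With 1 library per condition this difference has no replicate check, the reads compare those libraries and not the conditions, and the intervals cover counting error only. Of 13865 genes with at least 20 counts in the higher library, 1878 were at least 2-fold higher and 1570 at least 2-fold lower at 48 h. Scaling by library totals gave 2418 and 957 and moved the median log2 ratio of all genes from -0.09 to 0.14. Against both parental libraries 1442 were higher and 773 lower.

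Set against 10000 random lists of the same size and expression, 11 of 28 lists lay outside the central 95% at 48 h. Lists also lay outside it when untreated Parental_2 was set against Parental_1, so such a position is not by itself a sign of the drug. Percentiles there were 0 for erythroid, 0.2 for interferon, 0.6 for antigen presentation and 0.6 for cholesterol genes. They were 98.7 for anthracycline targets, 99.2 for the BCL2 family, and 100 for granulocyte and integrated stress genes. Interferon response genes had a median log2 ratio of 1.31 (percentile 100), with 18 of 27 at least 2-fold higher and 0 lower. RSAD2 was 20.2-fold higher (14.7 to 28.4) and IFI6 22.5-fold (11.7 to 49.7). Erythroid genes had a median of 0.96 (percentile 100), with 16 of 34 higher and 0 lower. The carbonic anhydrase CA1 was 23-fold higher (16.4 to 33.4) and the membrane skeleton protein EPB42 23.6-fold (15 to 39.5). Against Parental_1 the erythroid median was 0.25, with 9 members at least 2-fold higher, and in Parental_2 it lay at -0.81 relative to Parental_1. Epithelial and fibroblast genes had a median of 1.34 (percentile 100) over 6 measured, with COL1A1 17.1-fold higher (10.2 to 30.9) and CDH1 at 128 counts against 1 (log2 ratio 5.18, 4.09 to 11.91). Granulocyte and monocyte genes were at 0.57 (percentile 98.3), mitochondrially encoded genes at 0.30 (percentile 100), lysosome genes at 0.21 (percentile 99.9), with the protease CTSB at 2.09 (2.01 to 2.17), and proliferation genes at 0.13 (percentile 99.9), with E2F1 at 1.61 (1.47 to 1.75). Against Parental_1 all 11 lists stayed outside the central 95%. The medians there were 1.05 for interferon, 0.82 for epithelial and fibroblast, 1.32 for granulocyte and monocyte, 0.32 for lysosome and 0.09 for proliferation genes. That of mitochondrially encoded genes changed sign, to -0.04, at percentile 98.8. Of the genes named here IFI6 was at 2.72 against Parental_1, CA1 at 2.96, EPB42 at 3.30, RSAD2 at 4.96, CDH1 at 4.50 and E2F1 at 0.73 on the log2 scale.

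Integrated stress and unfolded protein response genes had the lowest median, -2.07 (percentile 0), with 17 of 22 at least 2-fold lower and 0 higher, and DDIT4, an inhibitor of mTORC1, at -4.32 (-4.43 to -4.21). Against Parental_1 their median was -0.90 (percentile 0), with 10 members at least 2-fold lower, and in Parental_2 it lay at 1.32 relative to Parental_1. STAT5, ERK and MYC outputs were at -0.58 (percentile 0.2), with 13 of 31 lower and 3 higher, STAT5B at -2.48 (-2.58 to -2.39) and SPRED1 at -2.29 (-2.48 to -2.11). Histone methyltransferases and demethylases were at -0.55 (percentile 0.2), with 8 of 48 lower and 2 higher, SMYD3 at -1.77 (-1.92 to -1.63) and EZH1 at 1.16 (1.02 to 1.31). Cholesterol and fatty acid synthesis genes were at -0.53 (percentile 2.1), with 6 of 28 lower. Against Parental_1 the medians of these last 3 lists were -0.76, -0.51 and -0.68. The other 17 lists lay inside the central 95%. Their medians were -0.02 for p53 targets, 0.43 for drug efflux, -0.32 for the ABCB1 neighbours, 0.19 for anthracycline targets, -0.15 for DNA repair and 0.50 for megakaryocyte genes. They were -0.64 for stem and progenitor genes, -0.66 for the 2 lymphoid genes measured, -0.50 for histone genes, and 1.06 for antigen presentation. They were 0.29 for NF-kB, -0.03 for the BCL2 family, -0.11 for NRF2, -0.20 for nuclear oxidative phosphorylation, -0.24 for glycolysis, 0.03 for mesenchymal genes and 0.30 for HOX genes. Scaling by library totals turned the sign of 5 of these medians, to 0.22 for p53 targets, 0.09 for DNA repair, 0.20 for the BCL2 family, 0.11 for NRF2 and 0.03 for nuclear oxidative phosphorylation. Against Parental_1 the median turned to 0.08 for p53 targets, -0.15 for drug efflux and 0.06 for lymphoid genes, and was 0.23 for antigen presentation and -0.02 for histone genes. Anthracycline targets (0.46, percentile 99.9), stem and progenitor genes (-0.74, percentile 1.6) and mesenchymal genes (0.23, percentile 98.6) lay outside the central 95% there. In these lists the proapoptotic BMF was at 3.57 (3.08 to 4.31), BCL2 at -2.89 (-3.67 to -2.38), the receptor KIT at 2.79 (2.19 to 3.72), ANGPT1 at -2.86 (-3.05 to -2.69), HK2 at -2.09 (-2.28 to -1.92) and VEGFA at -2.02 (-2.11 to -1.94). Against Parental_1 BMF was at 2.13, BCL2 at -1.84, KIT at 4.00, ANGPT1 at -1.84, VEGFA at -0.60, DDIT4 at -2.98 and STAT5B at -1.65.

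The final comparison asked how far the difference in the clones lay in the direction of the short exposure. CPXM1, BTG2 and RSAD2 were higher in both, ABCB1 stood at 8.43 in the clones and 0.34 at 48 h, and ALDH1A1 at -5.86 in the clones and 1.19 (1.03 to 1.36) at 48 h. Across 13768 genes, each ratio taken within its own table, Pearson's r was 0.41, Spearman's rho 0.38, the covariance 0.38, and 64.6% of genes had the same sign. Over 9725 genes with at least 100 counts in every group r was 0.29 and the covariance 0.12, and with ATC2 alone r was 0.28. Over 50 simulations unchanged groups gave r between -0.03 and 0.03 and a covariance of 0. Every library was drawn independently there, so an r near 0 was set by the design where no library is shared. The simulation held no difference between the parental libraries and cannot show what such a difference would give. With both ratios against Parental_1, r was 0.56 and the covariance 0.53, beside simulated values of 0.63 and 0.35. With the parental libraries exchanged r was 0.27. Only genes with at least 20 counts in Parental_2 or the 48 h library entered. A gene near 0 in parental cells therefore entered only if it was higher at 48 h. The genes at least 2-fold higher in all clones numbered 1068 in their own comparison and 625 here. Of these 625 and the 1798 higher at 48 h, 374 were shared, against 81.6 for independent lists. Part of that excess may be set by the filter, so it does not measure the overlap alone. Of 153 and 1566 lower genes 47 were shared, against 17.4. Genes higher in the clones and lower at 48 h numbered 26, against 71.1, a shortfall to which the same filter may add. The reverse numbered 19, against 20. Genes are not independent replicates, and part of the overlap may come from libraries of the same parental sample.

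**Figure D4:**
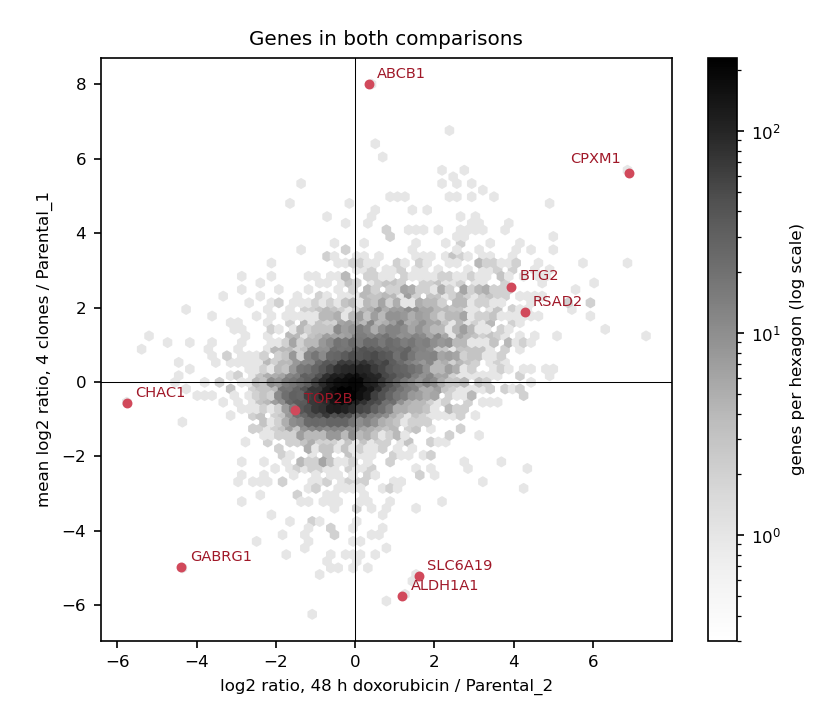
Mean log2 ratio of the 4 clones to Parental_1 (vertical) against the log2 ratio of the 48 h library to Parental_2 (horizontal) for the genes measured in both, with shade for genes per hexagon on a log scale. The cloud follows a Pearson's r of 0.41, and ABCB1, ALDH1A1 and SLC6A19 lie away from it.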

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

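No test in this part was planned on these values, and each difference was picked out by its size; about 1 in 20 groups stands apart in this way by chance. Among 109 values compared over the 4 clones, 10 had a clone apart from the other 3, measured as its gap to the nearest clone divided by the range of the 4. For single genes that share was 0.918 for COBL (2, 2, 0 and 2 counts, a gap of 2 reads that shows no clone apart), 0.832 for ABCC3 (ATC4 at 32 counts against 450 to 651), 0.892 for GABARAPL1 (ATC4), 0.884 for SPRED1 (ATC3 at 456 counts against 739 to 869), 0.836 for JUN (ATC3 at 2821 counts against 1651 to 1885), 0.88 for HOXB4 (ATC4) and 0.944 for S100A6 (ATC4 at 1264 counts against 2 to 4). For list medians it was 0.897 for histone methyltransferases and demethylases (ATC3 at -0.41), 0.851 for cholesterol and fatty acid synthesis (ATC2 at -1.58) and 0.917 for HOX genes (ATC1 at -0.27).

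ALDH1A1 and SLC6A19 lay in opposite directions in the clones and at 48 h. ALDH1A1 was between -6.34 and -5.16 in the 4 clones and at 1.19 at 48 h, or 1.30 against Parental_1, a gap of -6.94 on the log2 scale. SLC6A19 was between -5.87 and -4.89 in the clones and at 1.61 at 48 h, or 0.13 against Parental_1, a gap of -6.84. The difference between the groups was not tested, since the 48 h sample has 1 library.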

How the results depend on the processing

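Of the tests here, those that used the other parental library, or both, and all those of named genes at 48 h were chosen after the results were seen; the rest were chosen before the data were examined. For the clones against parental cells, 0 genes higher and 0 lower became 448 and 95 with DESeq2 and 11 and 8 without a filter on low counts, and stayed at 0 and 0 with limma-voom, size factors, library totals, a filter of 1 CPM, the 48 h library added and Parental_2 in place of Parental_1. Leaving out each clone gave 0 to 49 higher and 0 to 35 lower, the highest without ATC4. With both parental libraries as replicates 252 and 96 were called, and 1178 and 549 with DESeq2. With both, leaving out ATC1, ATC2, ATC3 and ATC4 gave 110, 172, 45 and 823 higher and 27, 51, 15 and 354 lower. The second parental library adds a residual degree of freedom but no sample; the cause of the other changes was not tested. For the lists, 14 became 0 with an estimated correlation, 13 to 16 with each clone left out, 16 with both parental libraries and 17 with Parental_2. Membership changed: p53 and granulocyte lists were lost in both of the last 2 settings, and the ABCB1 neighbours with Parental_2. Drug efflux, epithelial and histone genes entered in both, glycolysis with both libraries, and erythroid, integrated stress and HOX genes with Parental_2. All of these changes are for the preset correlation, and no list passed in either setting with an estimated correlation. Fry, which compares a list with no change and not with other genes, passed 0 in one direction and 6 for change in either direction.

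At 48 h, 1878 genes higher became 821 with at least 100 counts, from 10635 genes in place of 13865, 8 with edgeR on 7 libraries and 751 on 3 libraries; 1570 lower became 957 with library totals, 773 against both parental libraries, and 0 and 460 with edgeR on 7 and 3 libraries. Neither edgeR fit has a replicate of the 48 h sample, and on 3 libraries the only spread is between 2 libraries of 1 parental sample, so those calls rest on no replicate samples. Other settings gave 1442 to 2418 higher and 1282 to 1600 lower, and 11 to 14 lists. The correlation of 0.41 became 0.27 with the parental libraries exchanged, 0.56 with both ratios against Parental_1, 0.60 against Parental_2, where a library is shared, and 0.29 over genes with at least 100 counts, and ran from 0.39 to 0.45 with each clone left out.

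Of 77 named genes of the clones 75 kept their sign in every setting that tested them; the 1 CPM filter tested 73, and both parental libraries without ATC1, ATC2 and ATC3 75, 75 and 76. ATF3 turned to -0.38 with Parental_2, and H19 to -2.17 with limma-voom and -3.38 without ATC4 and with both parental libraries. With each clone left out H19 ran from -3.85, without ATC4, to 1.85. Of 91 named genes at 48 h 87 kept their sign; against Parental_1 TNFRSF10B turned to 0.31, RARG to -0.03, SETD7 to 1.14 and WIPI1 to 0.58, and the cause was not tested. No paired analysis was possible because the groups share no more than 1 replicate number. The authors' adjusted p-values, other pseudocounts for normalised units, and both parental libraries within 1 table were not run, since the tables give no p and hold counts, with 1 parental library each. Depth limits genes under about 20 counts, and at 48 h no replicate measures the spread.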

Other observations

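The tests of library size, of genomic DNA by reads per kilobase, of the ABCB4 paralog and of scaling were set out before their results were seen; every other test in this part was chosen afterwards. Genes higher both in all clones and at 48 h, chosen after their values were seen, included CPXM1 with a log2 fold change of 6.29 ± 1.6 in the clones and a ratio of 6.91 at 48 h, the basement membrane protein TINAGL1 with 4.39 ± 0.66 and 3.82, the receptor phosphatase PTPRF with 5.03 ± 0.76 and 2.92, the kinase BMX with 4.70 ± 0.88 and 3.04, and complement C3 with 3.26 ± 0.47 and 3.28. In edgeR's quasi-likelihood test the adjusted p was 0.319 for CPXM1, 0.199 for TINAGL1, PTPRF and C3, and 0.257 for BMX. The guanylate-binding genes GBP2 and GBP4, relatives of GBP5 that are induced by interferon, had log2 fold changes of 5.44 ± 1.18 and 6.42 ± 1.88 in the clones (adjusted p = 0.278 and 0.369 in the same test), with 18 and 24 counts in Parental_1, 1114, 910, 1195 and 211 for GBP2 and 2831, 3970, 2038 and 176 for GBP4 in ATC1 to ATC4. ATF5, a stress-responsive transcription factor, was lower in both, at -1.42 ± 0.24 (adjusted p = 0.22) and -2.26, as was LIN28B at -1.31 ± 0.25 (adjusted p = 0.262) and -1.81.

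Runs of neighbouring genes stood apart in other places too, and some of them were shared between clones. ATC1 was lower over 63 genes on chromosome 6 from 37482920 to 49463191 (median log2 ratio -0.81) and over 63 genes on chromosome 1 from 228456979 to 248849517 (-0.79), ATC3 over 36 genes on chromosome 11 from 10750987 to 22830299 (-0.80), and ATC4 over 38 genes on chromosome 9 from 37879400 to 87731393 (-0.79) and 30 genes on chromosome 18 from 23452823 to 46266991 (-0.74). The median of the chromosome 6 block was 0.10, 0.11 and 0.09 in ATC2, ATC3 and ATC4. That of the chromosome 1 block was -0.44, -0.45 and -0.38 there, so this block was lower in every clone. A block on chromosome 17 from 41523617 to 42311943 had medians of -0.73, -0.86, -0.76 and -0.05 in ATC1 to ATC4. One on chromosome 19 from 50329653 to 52512154 had 1.27, 0.66, 0.74 and 0.50. Blocks numbered 3 higher and 7 lower in ATC1, 4 and 1 in ATC2, 1 and 4 in ATC3, 4 and 9 in ATC4, and 0 and 1 at 48 h. The parental libraries, which come from 1 sample, also gave 2 higher and 9 lower blocks, over 49 and 183 genes, when Parental_2 was set against Parental_1, so such runs are not by themselves a sign of a different genome.

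Genes around ABCB1 on 7q21 were higher in ATC2 and ATC4. Reads shared with the paralog ABCB4 are argued against, since without both genes the neighbours stood at percentile 99.54 of runs of adjacent genes in the lower of the 2 clones. Scaling or a few abundant genes are argued against as well, since the neighbours' median there was 1.62 relative to all genes of the clone while the central 95% of runs ended at 0.71. As a hypothesis, ATC2 and ATC4 may each carry more copies of part of the segment. Of the genes of the block defined in ATC2, 88.9% lay above the median in ATC4, against 59.3% in ATC1 and ATC3. The raised stretches differed between ATC2 and ATC4. PTPN12 and PHTF2 were at 1.26 and 1.02 in ATC2 and at 0.13 and 0.04 in ATC4. FZD1 and MTERF lay the other way, at -0.19 and 0.35 in ATC2 and at 1.64 and 1.78 in ATC4. Past the block, at ARPC1A, the running median was 1.025 in ATC2 and -0.347 in ATC4. DNA was not measured, and ATC1 and ATC3 had ABCB1 at 454 and 396 CPM with neighbours at 0.23 and 0.34.

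More genes had a read in the 48 h library than in Parental_2, and the clones had more too, by 17.1%, 19.2%, 9.2% and 16.5% in ATC1 to ATC4 after thinning. Thinned to 12537146 counts each, the 48 h library had 27546 genes with a read against 21934, an excess of 25.6%, which argues against library size as the cause. Reads from genomic DNA cannot be told apart from transcription at a low level: 112 of all 381 olfactory receptor genes had a read after thinning against 44 in Parental_2 and 49 in Parental_1, which either would give, while their reads per kilobase, scaled to library size, were 0.131, 0.119 and 0.183, with 55.5%, 72.6% and 64.2% of them from OR51B5 and OR51B4. Receptors without a parental read carried 0.313 of the reads per kilobase of other such genes, below the bound of 0.5 set beforehand, but that bound was wrong because these genes were chosen for having no parental read and the pattern counts genes, not reads. The exposure itself cannot be told apart either, with 1 library per condition and an excess of 17.6% over Parental_1.

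Integrated stress genes were lower at 48 h, with a median of -2.07. Against Parental_1 the median was -0.90, at percentile 0 of matched random lists. Between the untreated libraries it differed more, with Parental_2 at 1.32 above Parental_1. These values therefore cannot decide whether a difference between parental libraries is the whole cause. A few abundant genes are argued against, since they shift the other genes by -0.04. An effect of the 48 h exposure cannot be told apart from other differences between single libraries. The state of the parental culture when it was sampled stays open and untested.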
